A study of Macaca mulatta with 35 samples.

How the data were processed

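The series measured total RNA of 3 cell types of the rhesus monkey ovary by RNA sequencing. Per the labels' protocols, ovaries were recovered from adult females at necropsy, and cumulus cells, granulosa cells and oocytes were taken from single antral follicles, the follicles that contain a fluid-filled cavity. RNA was extracted with the PicoPure kit and amplified with the Ovation RNA-Seq System v2, per the labels' protocols. The amplification step copies the small RNA yield of few cells, so that counts are not independent molecules. All intervals and floors given here therefore cover counting error only. Reads were converted with bcl2fastq 2.19.1 and quantified with kallisto 0.44.0, per the submitters' processing notes. The genome build and the annotation behind the transcript index are not given in the sources used here.

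Each library came with a table of 49537 transcript IDs. The deposited estimated counts are kallisto's assignment of reads to transcripts, in which a read that fits several transcripts is shared among them, per the file headers and the submitters' processing notes. The deposited TPM values, which scale by length and library total, were made by the authors from the same counts and effective lengths, per the file headers, and were not used in any test. The deposited transcript lengths and effective lengths were identical in all 35 tables. Estimated counts were rounded to whole numbers. For 8563 transcripts they were already whole in every library, within 1e-06, and these held 35.8% of all counts. For the others, a low or 0 value can reflect how reads were divided among transcripts of the same gene. The deposited values have a limited number of digits, so very large estimates, as of the most abundant transcript, appear whole even where reads were shared. Transcripts at 0 in every library count as whole too. The 35.8% is therefore not the share of counts assigned without division.

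The files do not pair transcripts with genes. Of the 49537 IDs, 0 matched the table of gene names and 0 matched the table of RefSeq genes used here. The design fixed before the data were examined had asked for counts summed per gene, with transcripts taking the place of genes if no annotation could be joined, and all tests were made per transcript ID. The gene lists fixed before the data were examined (steroidogenesis, cholesterol synthesis, hormone receptors, cell cycle, cumulus expansion, matrix, metabolism, meiotic maturation, maternal effect and others) and the marker lists for oocyte, granulosa, theca, immune, endothelial, red blood and surface epithelial cells could therefore not be tested. No transcript was given a gene name.

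The 35 libraries fell into 9 groups of cell type and follicle size, as the labels give them: 3 libraries of cumulus cells from small follicles and 4 libraries in each of the other 8 groups. No library was left out. The labels do not say which libraries came from the same animal or follicle. The p-values then measure the spread between these libraries, which may be partly technical. No pair of libraries within a group agreed within counting noise: the lowest chi-square per degree of freedom was 69.4. Separate amplifications of the same RNA would exceed counting noise too and are not excluded by this, and pairs of different groups were not compared.

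The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust fit) with TMM normalization, edgeR's default filter on low counts by group with a minimum count of 10, and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. Size comparisons within a cell type were fitted on the libraries of that cell type alone, 11 for cumulus cells, 12 for granulosa cells and 12 for oocytes. Comparisons of cumulus with granulosa cells used their 23 libraries, and the comparison of oocytes with both used all 35. This gave 15 comparisons. The named transcripts were, by a rule fixed before the data were examined, those past the threshold with the smallest p in each direction and a mean of at least 10 counts per library in the higher group. Since the IDs carry no gene name, at most 2 higher and 2 lower are printed per comparison. Levels are CPM, counts scaled to the library total, with TMM factors of the same fit, except that levels per group of the 2 transcripts called between sizes or within small follicles, floors and ratios use factors over all 35 libraries, and the ordination used log2 CPM with a prior count of 2. An absence of counts is set against a floor of 3 counts over the group.

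The tests were tried on simulated counts for the same transcripts and library sizes, with 200 transcripts changed by known factors, 50 at each factor. Libraries were drawn independently around the mean of each transcript over all libraries of the fit, with no structure by library number. At 4-fold, 8% of the changed transcripts were recovered for cumulus cells large against small, 0% for granulosa cells and 16% for oocytes. At 16-fold these shares were 48%, 32% and 44%. For cumulus against granulosa cells over all sizes, 46% were recovered at 4-fold and 76% at 16-fold, and for oocytes against both somatic types 52% and 84%. Among unchanged transcripts, false calls numbered 1, 1 and 4 in the size comparisons of cumulus cells, granulosa cells and oocytes. They numbered 4 for cumulus against granulosa cells and 21 for oocytes against both somatic types. Unadjusted p values under 0.05 covered 6.32% and 6.59% of unchanged transcripts in these last comparisons. With at most 200 right calls possible, the false share for oocytes against both somatic types exceeded the 0.05 threshold in that simulation. In the simulated large against small comparisons this cover was 4.79%, 4.34% and 4.44% for cumulus cells, granulosa cells and oocytes. The real comparisons gave 3.72%, 2.17% and 1.90% of all tested transcripts. The simulated test thus did not behave like the real one, and its recovery is a rough guide only.

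Alternatives were other normalization factors (RLE), no filter, DESeq2 1.42.0, limma 3.58.1 with sample weights, all 35 libraries in 1 fit, the library number as a block and leaving out each library. Added after seeing the data were fits on transcripts with whole counts alone, fits without the 11 transcripts that each held over 1% of all counts, fits with the share of oocyte-predominant counts as a covariate or without the libraries where it passed 0.2%, and the number alone as a block between cell types. Titles number the libraries 1 to 4 within a group. In granulosa cells all 12 pairs of libraries with the same number deviated together from their group means across transcripts, with correlations from 0.12 to 0.43, so that the numbers were taken to pair those libraries, on this measure alone.

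Also added after seeing the data was a set of 319 oocyte-predominant transcripts. In each of these the lowest oocyte library lay over 8-fold above the highest granulosa library, and the oocyte mean on the log2 CPM scale was above 5. Cumulus libraries played no part in the choice, and each granulosa library was measured with a set made without it. A matching set of 206 somatic-predominant transcripts was higher in every cumulus and granulosa library than in every oocyte library, with means over 8-fold apart, and each oocyte library was measured with a set made without it. Shares of single libraries rest on at least 20780298 counts, and their 95% Wilson intervals were at most 0.037 percentage points wide. Variance across libraries was split by size and by number on squared distances of log2 CPM, with exact permutation tests.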

Results

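RNA was sequenced from cumulus cells, which surround the oocyte, from granulosa cells, which line the wall of the follicle, and from oocytes of the rhesus monkey. Each cell type was taken from small, medium and large antral follicles, and the series asks how gene expression of the 3 cell types differs as these follicles grow. There were 3 libraries of cumulus cells from small follicles and 4 libraries in each of the other 8 groups, 35 in all. Libraries are named here by cell type, follicle size and the number in their title. Total estimated counts ran from 20780298 in oocyte large 4 to 52350303 in oocyte medium 2, with a median of 28839612. Cumulus libraries held 25942122 to 31971313 and granulosa libraries 22067108 to 33772578. At this depth 3 counts in a group correspond to 0.033 CPM (counts scaled to the library total) in the granulosa small libraries. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of at least 69.4 between any pair. The files name transcripts by Ensembl ID and do not pair them with genes, so each value below belongs to a transcript and no gene name is given.

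The most abundant transcript of the series, 836 bases long, held 31.0% ± 6.61 (SD, n = 12) of granulosa counts, 16.9% ± 2.78 (SD, n = 11) of cumulus counts and 8.23% ± 1.5 (SD, n = 12) of oocyte counts. All 3 differences between cell types passed a two-sided permutation test of the means (p = 2e-05 each, adjusted p = 0.00011 over 22 tests of library measures, the smallest these permutations can give before adjustment). The second most abundant transcript, 1568 bases long, went the other way: 11% ± 2.44 in cumulus cells (SD, n = 11) against 3.55% ± 2.59 in granulosa cells (SD, n = 12, permutation test, adjusted p = 0.00011). In oocytes it held 13.2% ± 11.2 (SD, n = 12), with a range from 0.992% to 44.8%, and no difference from cumulus cells passed the test (permutation test, adjusted p = 0.937). More transcripts reached 10 counts in cumulus libraries, 27466 ± 626 (SD, n = 11), than in granulosa libraries, 25483 ± 1562 (SD, n = 12, permutation test, adjusted p = 0.00169), or oocytes, 25933 ± 1446 (SD, n = 12, permutation test, adjusted p = 0.00396). Across follicle sizes, depth, the number of transcripts and the share of the top transcript gave no difference past the threshold in any cell type (exact permutation tests, lowest adjusted p = 0.258). All these permutation tests treat libraries as independent. Libraries of 1 number shared deviations in granulosa cells and oocytes (below), so the p-values between cell types may be too small.

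**Figure D1:**
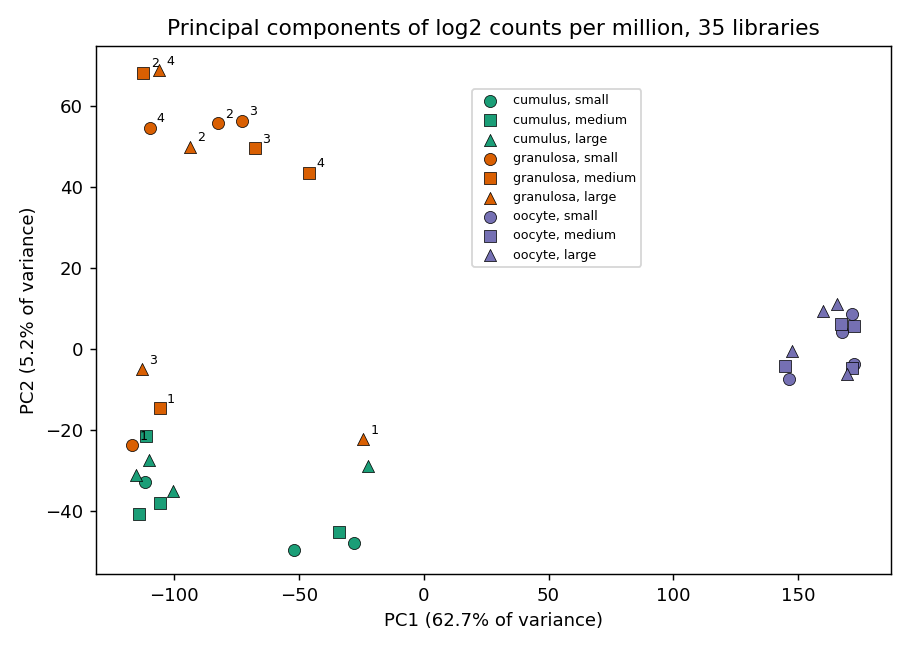
Principal components of log2 CPM over the 2000 most variable transcripts, 1 point per library, with PC1 (62.7% of the variance) on the x axis and PC2 (5.2%) on the y axis, colour for cell type and shape for follicle size, and the library number beside each granulosa point. Oocyte libraries lie to the right at PC1 of 145 and above, all cumulus libraries lie below 0 on PC2, and of the granulosa libraries small 1, medium 1, large 1 and large 3 lie below 0 on PC2 as well.

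The comparison of oocytes with the mean of cumulus and granulosa cells separates germ cells from the somatic cells around them. Of 37702 transcripts tested, 12924 were higher and 12814 lower in oocytes (edgeR quasi-likelihood test, adjusted p under 0.05), and 8433 of the higher and 8041 of the lower ones differed by more than 4-fold. The transcripts higher in oocytes held 69.5% ± 4.27 (SD, n = 12) of oocyte counts, 30.7% ± 2.54 (SD, n = 11) of cumulus counts and 15.4% ± 5.60 (SD, n = 12) of granulosa counts. Those lower in oocytes held 74.7% ± 6.73 of granulosa counts, 58.5% ± 2.81 of cumulus counts and 21.3% ± 3.09 of oocyte counts. The transcript ENSMMUT00000023182.4, 5520 bases long, stood at 60.4 ± 9.29 CPM in oocytes (SD, n = 12) and 5.41 ± 1.21 in somatic cells (SD, n = 23). Its log2 difference was 3.48 with an SE of 0.12 (edgeR, adjusted p = 4.09e-19), and every oocyte library lay above every somatic one. ENSMMUT00000021805.4, 2587 bases long, stood at 178 ± 33.2 against 14.9 ± 4.14 (log2 difference 3.62, edgeR adjusted p = 4.61e-19). The lowest p among transcripts lower in oocytes belonged to ENSMMUT00000096134.1, 5485 bases long, at 2.08 ± 0.485 CPM in oocytes against 140 ± 34.1 in somatic cells (log2 difference -6.07, SE 0.19, edgeR adjusted p = 2.36e-19). ENSMMUT00000099651.1, 3795 bases long, stood at 2.06 ± 0.487 against 22.7 ± 5.90 (log2 difference -3.42, edgeR adjusted p = 3.44e-17). In 4053 transcripts every oocyte library lay above every somatic library and in 1722 every one lay below. Chance would give 2.4e-07% of transcripts if libraries were independent, which those of 1 number may not be.

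Transcripts of the oocyte-predominant set held 8.32% ± 1.78 (SD, n = 12) of oocyte counts. In 17 of the 23 somatic libraries they held between 0.0473% and 0.0954% of counts. They held 0.384% in cumulus small 1, 0.304% in cumulus small 2, 0.481% in cumulus medium 2, 0.528% in cumulus large 3, 0.277% in granulosa medium 4 and 0.513% in granulosa large 1. These 6 libraries thus reached between 3.33% and 6.35% of the oocyte level, and the other 17 at most 1.15%. No difference in these shares passed the test between cumulus and granulosa cells (permutation test, adjusted p = 0.474) or across sizes within cumulus (exact permutation test, adjusted p = 0.937) or granulosa cells (exact permutation test, adjusted p = 0.937). Somatic-predominant transcripts held 2.86% ± 0.41 of cumulus counts (SD, n = 11), 2.72% ± 0.684 of granulosa counts (SD, n = 12) and 0.239% ± 0.107 of oocyte counts (SD, n = 12), with the highest oocyte value of 0.478% in oocyte small 2.

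**Figure D2:**
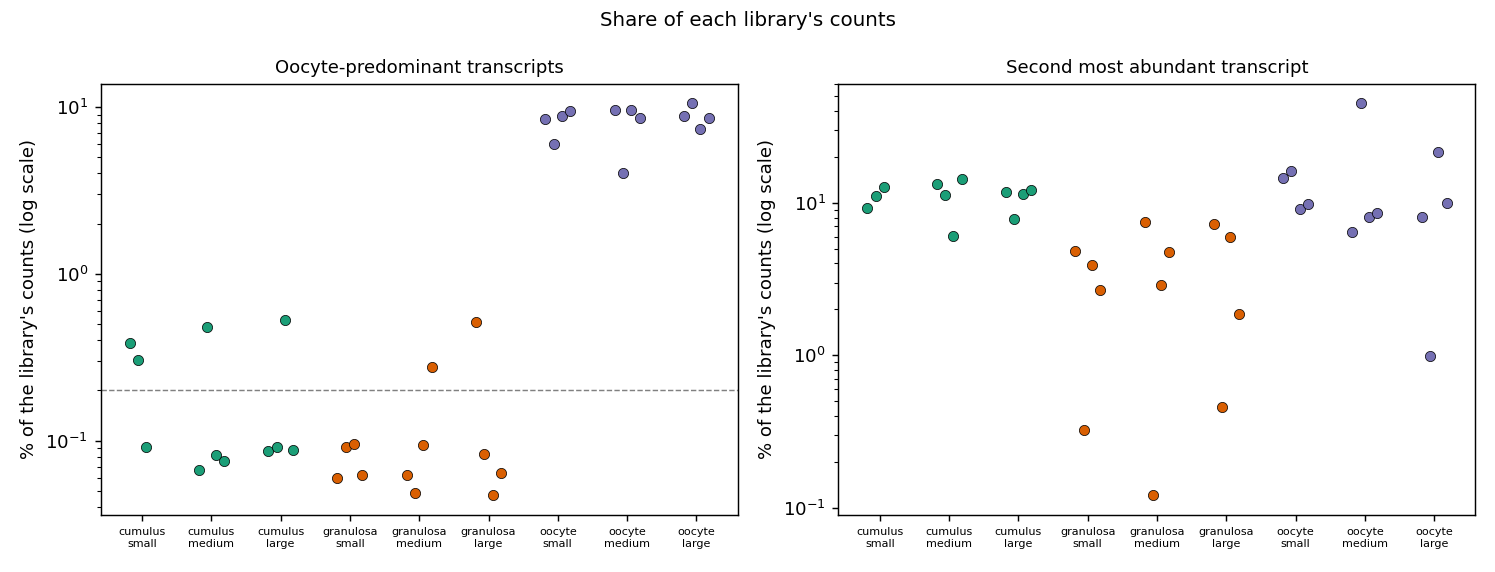
Share of each library's counts (y axis, percent on a log scale) on the 319 oocyte-predominant transcripts (left) and on the second most abundant transcript (right), 1 point per library, by cell type and follicle size on the x axis and in the order of the library numbers within a group, with a dashed line at 0.2%. On the left 6 somatic libraries lie above the line, between 0.277% and 0.528%. On the right oocyte medium 2 stands at 44.8%, and the granulosa libraries of number 2 lie between 0.122% and 0.461%.

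Cumulus and granulosa cells differ by their place in the follicle, next to the oocyte or along the wall. Averaged over the 3 sizes, 3261 transcripts were higher and 3324 lower in cumulus than in granulosa cells, of 34521 tested in 23 libraries (edgeR quasi-likelihood test, adjusted p under 0.05). Differences of more than 4-fold were found for 479 of the higher and 749 of the lower transcripts. The transcripts higher in cumulus cells held 18.7% ± 2.03 of cumulus counts (SD, n = 11), 6.63% ± 3.77 of granulosa counts (SD, n = 12) and 16.3% ± 3.62 of oocyte counts (SD, n = 12). The transcripts higher in granulosa cells held 52.9% ± 8.29 of granulosa counts, 30.3% ± 3.93 of cumulus counts and 20.2% ± 1.78 of oocyte counts. Of 3259 higher in cumulus cells and tested in both contrasts, 520 were called higher and 2028 lower in oocytes, where independent calls give 988 and 1210. Of 3324 higher in granulosa cells, 1265 were higher and 1152 lower in oocytes, where independent calls give 1007 and 1234. Both contrasts share the somatic libraries, so their calls are not independent. ENSMMUT00000069743.2, 1535 bases long, stood at 16.4 ± 3.85 CPM in cumulus cells (SD, n = 11) and 2.56 ± 1.87 in granulosa cells (SD, n = 12), with a log2 difference of 2.74 and an SE of 0.34 (edgeR, adjusted p = 0.00149). ENSMMUT00000103129.1, 3960 bases long, stood at 25.2 ± 6.04 against 8.0 ± 3.46 (log2 difference 1.64, edgeR adjusted p = 0.00149). In both, every cumulus library lay above every granulosa library. ENSMMUT00000032718.4, 5646 bases long, had 8.08 ± 5.84 CPM in granulosa cells (range 0.460 to 20, n = 12), while its only counts in cumulus cells were 10 in a single large-follicle library (edgeR, adjusted p = 0.00149). ENSMMUT00000080038.1, 1934 bases long, stood at 1.59 ± 1.43 in cumulus cells and 3.77 ± 1.54 in granulosa cells (fitted log2 difference -3.20, edgeR, adjusted p = 0.00149). The small follicles carried most of this log2 difference. Its group means were 0.009 CPM in cumulus against 4.32 in granulosa cells in small, 2.28 against 2.83 in medium and 2.15 against 4.43 in large follicles. Estimated counts of these 4 transcripts were not whole numbers, so part of their reads was shared with other transcripts. In 39 transcripts every cumulus library lay above every granulosa library and in 22 every one lay below. Chance would give 0.000148% if libraries were independent, which those of 1 number may not be. The higher and lower counts were 2922 and 4025 with RLE factors, 5121 and 3665 by limma with sample weights, and 178 and 488 on transcripts with whole counts. With size and number together as a block the count fell to 1066 (556 higher and 510 lower), and with the number alone as a block it was 6635 (3773 higher and 2862 lower). The count of 6585 calls fell to 4259 without cumulus small 2, and to 40 without the 6 libraries that held over 0.2% of oocyte-predominant counts, which leaves 1 cumulus library from small follicles. Leaving out 6 libraries at random, as many per group, gave 12 to 2644 calls (median 50, 24 draws).

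Within a single follicle size the contrast of cumulus with granulosa cells passed the threshold far less often. In small follicles (3 against 4 libraries) 0 transcripts were higher in cumulus cells and 1 was lower, with 4838 at an unadjusted p under 0.05 (edgeR quasi-likelihood test) and 1730 calls by DESeq2. The transcript was ENSMMUT00000080038.1, which had 1 count in all 3 cumulus libraries and 382 counts in the 4 granulosa libraries, a ratio of 447 after scaling (exact 95% counting interval 79.7 to 17700, fitted log2 difference -8.30, edgeR adjusted p = 0.00117). This call was lost with limma (log2 difference -7.81, adjusted p = 0.0719), with size and number as a block (-8.66, 0.0691), with all 35 libraries in 1 fit (-8.31, 0.142) and without the libraries over 0.2% (-9.90, 0.0977), and its adjusted p was 6.75e-09 with DESeq2. In medium follicles (4 against 4) edgeR called 0 transcripts, with a lowest adjusted p of 0.0556, while 8193 had an unadjusted p under 0.05 and DESeq2 called 5540. That count of 0 rose to 2056 without granulosa small 1, to 2003 without granulosa medium 1, to 1497 without granulosa large 4 and to 917 without granulosa large 3. In large follicles edgeR called 0 transcripts, with 2966 at an unadjusted p under 0.05, and DESeq2 called 449. Whether this contrast changed with size was tested only between large and small follicles.

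Whether follicle growth acted alike in both somatic cell types was asked with the difference between their large against small changes. At an unadjusted p under 0.05 there were 1336 of 34521 transcripts, or 3.87%, below the share of 0.05 expected without any effect. In this test 1 transcript passed, ENSMMUT00000080038.1 (edgeR quasi-likelihood test, log2 difference of changes 7.27, SE 1.05, adjusted p = 0.0344). In cumulus cells it had 1 count over the small libraries and 301 over the large ones, a ratio of 228 (exact 95% counting interval 40.6 to 9030). In granulosa cells it stood at 4.32 ± 1.72 CPM in small (SD, n = 4) and 4.43 ± 1.49 in large follicles (SD, n = 4). The call was lost in 15 of the 23 fits that left out 1 library: each cumulus large and each granulosa large library, cumulus small 1 and 3, granulosa small 1 and 3, and granulosa medium 2, 3 and 4 (adjusted p from 0.0238 to 0.177 over the 23 fits). It was also lost with size and number as a block (adjusted p = 0.618), with limma (1), with all 35 libraries in 1 fit (0.843), with the oocyte share as a covariate (0.0852) and without the libraries over 0.2% (0.259), while DESeq2 gave 1.6e-05. Across 27843 transcripts, the large against small fold changes of cumulus and granulosa cells had a Pearson correlation of 0.015 and a Spearman correlation of 0.088, and 55.3% had the same sign. Transcripts are not independent replicates, and no p is given for this correlation. The median SE of these log2 changes was 0.65 in cumulus and 0.69 in granulosa cells, with 0 and 1 transcripts called. Noise of this size can give a low correlation whether or not the responses are shared, so it does not answer the question.

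Cumulus cells of different follicle sizes showed 0 transcripts past the threshold in any of the 3 size comparisons, of 31869 tested (edgeR quasi-likelihood test). At an unadjusted p under 0.05 there were 1177 for medium against small, 1165 for large against medium and 1187 for large against small. These were between 3.66% and 3.72% of those tested, below the share of 0.05 expected without any effect. DESeq2 called 205, 109 and 190 transcripts. The lowest adjusted p values by edgeR were 0.36, 0.145 and 0.115.

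Granulosa cells showed 1 transcript past the threshold, ENSMMUT00000040891.3, 4305 bases long, of 28721 tested (edgeR quasi-likelihood test). It had 0 counts in all 4 small-follicle libraries. In medium follicles it stood at 3.80 ± 0.594 CPM (SD, n = 4, factors over all 35 libraries), a mean 114-fold above a floor of 3 counts over the small group (edgeR, adjusted p = 0.0322). In large follicles it stood at 3.10 ± 1.23 CPM (SD, n = 4), a mean 93.3-fold above this floor (edgeR, adjusted p = 0.0401). Both comparisons use the same small-follicle libraries, and both calls were lost whichever 1 of the 12 libraries was left out (adjusted p from 0.0639 to 0.191 for medium and from 0.0745 to 0.217 for large follicles). Its estimated counts were not whole numbers, so its 0 values may reflect how reads were divided among transcripts, which the floor does not cover. In cumulus cells the same transcript, on the same scale, ranged from 0 to 7.34 CPM in small follicles and from 2.57 to 9.09 in medium follicles, and it was not called there. With the library number as a block, 0 transcripts passed in either comparison, and the adjusted p of this transcript became 0.766 for medium and 0.461 for large follicles. Its fitted log2 difference, which is no bound since the small group is at 0, was 9.54 without and 9.57 with the block for medium, and 9.23 and 9.18 for large follicles. Both calls were also lost with limma (adjusted p = 0.999 and 1), with all 35 libraries in 1 fit (1 and 0.965), with the oocyte share as a covariate (0.138 and 0.176) and without the libraries over 0.2% (0.447 and 0.506), and that for large follicles with no filter (0.0504), while DESeq2 gave 2.26e-11 and 5.67e-10. Large against medium granulosa cells gave 0 calls by edgeR, with 314 transcripts at an unadjusted p under 0.05, and 37 calls by DESeq2. For medium against small and large against small there were 654 and 622 at an unadjusted p under 0.05, and 27 and 41 calls by DESeq2. The counts at an unadjusted p under 0.05 were 1.09% to 2.28% of those tested, below the share of 0.05 expected without any effect.

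**Figure D3:**
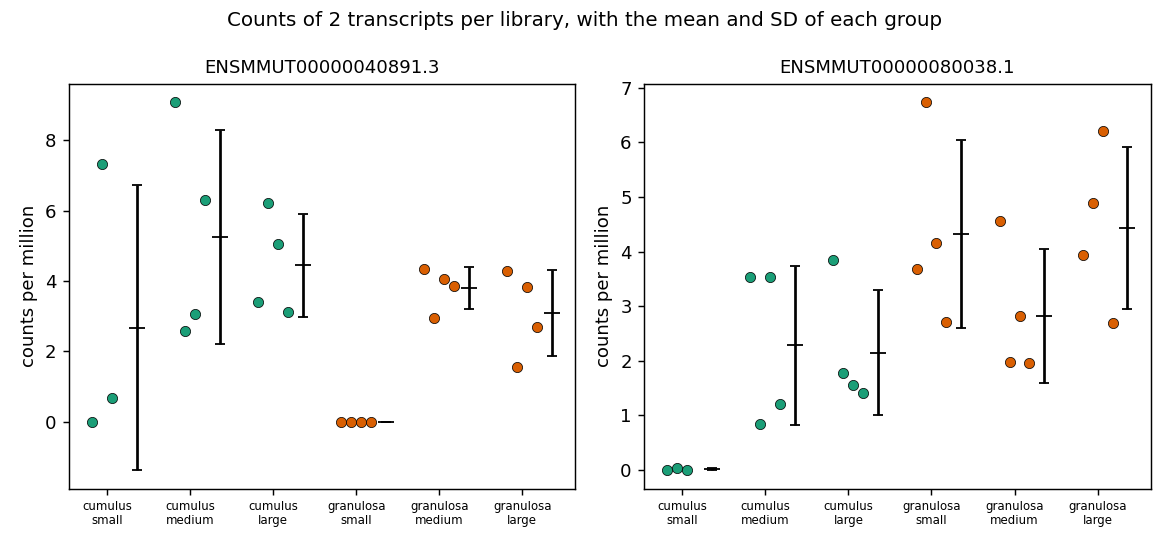
CPM (y axis, TMM factors over all 35 libraries) of the 2 transcripts called between sizes or within small follicles, 1 point per library by cell type and follicle size (x axis), with the mean and SD of each group as a bar beside the points. The 4 granulosa small libraries hold 0 counts of ENSMMUT00000040891.3, and the 3 cumulus small libraries hold 1 count of ENSMMUT00000080038.1 in all.

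Oocytes of different follicle sizes showed 0 transcripts past the threshold in all 3 comparisons, of 28769 tested in 4 libraries against 4 (edgeR quasi-likelihood test). At an unadjusted p under 0.05 there were 362 for medium against small, 609 for large against medium and 547 for large against small. These were 1.26%, 2.12% and 1.90% of those tested, below the share of 0.05 expected without any effect. DESeq2 called 37, 40 and 44 transcripts. The lowest adjusted p by edgeR was 0.397.

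Over the whole profile, follicle size accounted for 19.6% of the variance between cumulus libraries, 14.2% between granulosa libraries and 15.7% between oocyte libraries, where unrelated labels give 20%, 18.2% and 18.2% (exact permutation tests, p = 0.57, 0.967 and 0.992, adjusted p = 0.854, 0.992 and 0.992 over 6 tests). The library number accounted for 43.9% of the variance in granulosa cells and 34.7% in oocytes, against 28.6% and 28.1% by chance (exact permutation tests within size, p = 0.00174 each, adjusted p = 0.00521, the smallest p these permutations can give). In cumulus cells it accounted for 30.0% against 30.1% by chance (exact permutation test, p = 0.51, adjusted p = 0.854). That test rests on the numbers as given, and some cumulus small libraries matched the profile of another number (below). It does not show that cumulus libraries lack structure by number, since 8 of 11 matched the oocyte profile of their own number. Size labels were permuted over all libraries of a cell type, without regard to the numbers. Number held more variance than chance in granulosa cells and oocytes. The size shares below chance there can come from this structure, so their p-values do not show that size had no effect. Among granulosa libraries the second most abundant transcript held 0.122% to 0.461% of counts in the 3 libraries of number 2, and 1.87% to 7.47% in the other 9.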

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

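The tests of library depth and follicle size as explanations of the raised oocyte counts were chosen after the shares had been seen, and the test of oocyte RNA before its result was seen. In groups of 4 libraries, 6 measures of each library were searched for a value far from the other 3, by the gap to the nearest of them over the group's whole range (Dixon's test). Of 48 such searches 5 stood out, in 4 libraries, where chance gives about 1 in 20, or 2.4.

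In oocyte medium 2 the total count was 52350303, against 24639314 to 26405340 in the other 3 libraries of its group, and the second most abundant transcript held 44.8% of its counts, against 6.45% to 8.61%. Without that transcript the library held about 28900000 counts, against 22500000 to 24700000. Leaving the library out left all 3 oocyte size comparisons at 0 calls.

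Oocyte-predominant transcripts held 0.481% of counts in cumulus medium 2, 0.528% in cumulus large 3 and 0.513% in granulosa large 1, each far above the other 3 libraries of its group, which reached at most 0.0826%, 0.0921% and 0.0835%. With cumulus small 1, cumulus small 2 and granulosa medium 4, 6 libraries were raised. Depth alone did not set the raised libraries apart, since 2 of the 6 lay below the median depth of the other somatic libraries. The deepest cumulus library (cumulus small 1, 31971313 counts) and the deepest granulosa library (granulosa large 1, 33772578) were both raised, so a part played by depth stays open. Oocyte RNA carried into these libraries may be a source: the excess over the other libraries of the cell type followed the oocyte profile across the 319 transcripts with a Spearman rho of 0.598 in cumulus small 2 and of 0.772 to 0.865 in the other 5, and was above 0 for 277 to 305 of them, but the lowest rho fell between the bounds set beforehand (0.5 and 0.8), so that the test did not decide. The follicle size label is the same for all libraries of a group. Alone it does not account for cumulus medium 2, cumulus large 3 and granulosa large 1, which stood far above the others of their group. An added effect of size stays open as a biological explanation, with an exact permutation p of 0.84 in cumulus cells that excludes no effect.

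The large against small change of ENSMMUT00000080038.1 differed between cumulus and granulosa cells by 7.27 on the log2 scale in the test of the difference itself (adjusted p = 0.0344). The call was lost with the block (log2 difference 7.57, adjusted p = 0.618), limma (6.66, 1), all 35 libraries in 1 fit (7.27, 0.843), the covariate (6.98, 0.0852), without libraries over 0.2% (8.95, 0.259) and in 15 of 23 fits that left out 1 library. It rests on 1 count in the 3 cumulus small libraries, and 7 of 60 groupings with size labels permuted within each cell type gave at least 1 call.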

How the results depend on the processing

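The fits on whole counts, without dominant transcripts, with the oocyte share as a covariate, without libraries over 0.2% oocyte counts with the number alone as a block and without random libraries were chosen after seeing the data. Not run were the length offset, since effective lengths were identical in all libraries, and the tests of gene lists, since no transcript was joined to a gene. No direction reversed among the named transcripts. Unless a reason is given, the cause of a change was not tested.

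Oocytes against somatic cells gave 24254 to 26763 calls with RLE factors, no filter, DESeq2, limma, either block and without dominant transcripts, and 25152 to 25779 leaving out 1 library. On whole counts it gave 2814 of 3364 tested, fewer because fewer were tested. Cumulus against granulosa cells over all sizes gave 6947 calls with RLE factors, 5958 with no filter, 9565 by DESeq2, 8786 by limma, 6017 with all 35 libraries in 1 fit, 5365 with the covariate, 6635 with the number alone as a block and 6704 without dominant transcripts. It gave 666 of 2863 tested on whole counts, and 4259 (without cumulus small 2) to 8305 (without granulosa small 1) leaving out 1 library. Without the 6 libraries over 0.2% it gave 40, of which 30 were among the 6585. Leaving out 6 libraries at random, as many per group, gave 12 to 2644 calls with a median of 50 in 24 draws, and at most 40 in 10 of them, so that the loss of 6 libraries alone can give such a drop.

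DESeq2 gave 205, 109 and 190 calls in cumulus cells for medium against small, large against medium and large against small, 27, 37 and 41 in granulosa cells and 37, 40 and 44 in oocytes. For cumulus against granulosa cells it gave 1730 in small, 5540 in medium and 449 in large follicles, and 336 for the difference of changes. The all-library fit gave 0 and 0 calls for granulosa medium and large against small, 1 and 1 for oocyte large against medium and large against small, 909 for cumulus against granulosa cells in medium follicles and 0 for the difference of changes. Limma gave 0 and 0 for granulosa medium and large against small, 0 in small and 2328 in medium follicles, and 0 for the difference. No filter gave 0 for granulosa large against small. The covariate gave 0, 0 and 0 for these granulosa comparisons and the difference, and whole counts 0 for these and in small follicles. Without libraries over 0.2%, cumulus medium and large against small gave 1 and 1, the granulosa comparisons 0 and 0, small, medium and large follicles 6, 3 and 1, and the difference 2. The 6 calls in small follicles here, and the 1 call there in the all-library fit, are other transcripts than the 1 called in the report.

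With the replicate block, granulosa medium and large against small gave 0 and 0, cumulus against granulosa cells 1066 over all sizes (1048 among the 6585) and 0 in small follicles, and the difference 0; it changed no other call. The number alone as a block gave 3 in small and 1260 in medium follicles. Between cell types and within cumulus cells and oocytes the numbers were not taken to pair the libraries, since correlations of same-numbered pairs were over 0.1 in 1 of 10 cumulus, 9 of 12 oocyte, 1 of 11 cumulus and granulosa, 0 of 11 cumulus and oocyte and 0 of 12 granulosa and oocyte pairs. The best match bore the own number in 4 of 20 cumulus, 22 of 24 oocyte and 23 of 24 granulosa cases. In oocytes the choice rests on the cut of 0.1 alone. All 12 oocyte correlations were above 0 (0.028 to 0.263), and number held more variance than chance there, so a pairing of oocyte libraries stays open. The block left the oocyte size comparisons at 0 calls. Between cell types the cut missed structure by number. Of 12 granulosa libraries 11, and of 11 cumulus libraries 8, matched the oocyte profile of their own number (below). A pairing between cell types thus stays open too, and the main tests between cell types treat all libraries as independent.

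Leaving out 1 library gave 0 calls throughout for cumulus and granulosa medium against small and all oocyte sizes, and 0 to 1 for cumulus large against medium and large against small (1 without cumulus medium 4), granulosa large against medium and large against small (1 without granulosa large 1) and cumulus against granulosa cells in large follicles (1 without cumulus small 3 or granulosa large 1). The range was 1 to 6 in small follicles (6 without granulosa small 1), 0 to 2056 in medium follicles and 0 to 2 for the difference (2 without granulosa small 2). The correlation of large against small changes, 0.0147, was 0.0156 with RLE factors and 0.0321 at a mean of 50 counts, and went from -0.033 (without cumulus small 2) to 0.0956 (without granulosa small 3). Transcripts near the floor of 3 counts are limited by depth.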

Other observations

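The tests on library numbers and transcript length, the use of the planned block as a test of the few calls, the gaps of the cumulus libraries and the splits that keep libraries of 1 number together were chosen after the patterns had been seen, while those on a share of cumulus cells, on recovery in simulated data, on the covariate and on the remaining splits were set before their results were seen.

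Oocyte and granulosa libraries with the same number shared part of their deviations although they are different cells. Profiles of the 4 numbers were built from oocyte libraries alone, over 2372 transcripts that differed between numbers there. Of the 12 granulosa libraries, 11 matched the profile of their own number best, where 3 are expected (permutation of numbers within size, p = 0.00016, adjusted p = 0.00032 over 4 such tests). Built from granulosa libraries over 9173 transcripts, the profiles were matched by 12 of 12 oocyte libraries (permutation test, p = 8e-05). Of the 11 cumulus libraries, 8 matched the oocyte profile of their number, where 2.66 are expected (permutation test, p = 0.00293, adjusted p = 0.00296). A candidate explanation is that 1 number marks 1 animal, or 1 processing batch, in all 3 cell types; the labels say neither, and these tests cannot tell an animal from a batch. Same-sized and other-sized pairs of granulosa and oocyte libraries of 1 number deviated together about equally, with mean correlations of 0.029 and 0.039, so nothing here ties them to 1 follicle. Cumulus small 3 matched number 4 with both sets of profiles, with correlations of 0.223 and 0.221 against -0.0235 and -0.119 for number 3. Cumulus small 2 matched number 3 with both sets, with correlations of 0.0333 and 0.236 against 0.0293 and -0.039 for number 2. These 2 of the 3 cumulus small libraries also enter the block fits, the correlations of same-numbered cumulus pairs and the cumulus variance by number. All of these rest on the numbers as given.

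Granulosa libraries of number 1 lay toward the cumulus libraries: on a scale where the granulosa libraries of the other numbers stand at 0 and their cumulus libraries at 1, granulosa small 1, medium 1 and large 1 stood at 0.585, 0.403 and 0.378 on 126 transcripts high in cumulus cells, and at 0.956, 0.824 and 0.898 on 247 transcripts high in granulosa cells. A share of cumulus cells in the library would give 1 position on both sets, and the smallest gap was 0.371, or 0.364 with the cumulus libraries of number 1 as the upper end. The bound of 0.2 set beforehand ignored the spread of the cumulus libraries themselves. Cumulus medium 4 reached a gap of 0.503, against 0.371 to 0.52 in the granulosa libraries of number 1. With cumulus libraries of the own number as the upper end, the largest cumulus gap was 0.372, against 0.364 to 0.533. On both scales the smallest granulosa gap lay within the cumulus spread, so a share of cumulus cells stays open. Transcript length is argued against, with a largest absolute Spearman rho of 0.0734 between deviation and length, while an animal or batch shared by the number stays open and is in line with the 11 matches above; since animal and batch have no label, no biological explanation was tested. Granulosa large 3, at 0.376 on 102 and 0.875 on 198 transcripts chosen without number 3, lay on the same side and was the library that did not match its own number.

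Few transcripts were called between follicle sizes in any cell type. In simulated data the share of 4-fold changes recovered was at most 16% over the 3 cell types, 0% for granulosa cells. Changes of that size would mostly be missed if the real data behaved alike, but the simulation held no structure by number. The bound set beforehand (under 10% in each) was passed by oocytes, so the test did not decide. With the oocyte share as a covariate edgeR called 0 transcripts in the 6 cumulus and granulosa comparisons, and with the replicate block 0 in the 3 granulosa ones, where a bound of at most 5 had been set against each explanation; at this recovery a count of 0 excludes neither, and both stay open. With the block the transcripts at an unadjusted p under 0.05 went from 654 to 1342 for granulosa medium against small, from 314 to 473 for large against medium and from 622 to 1101 for large against small. Each count stayed below a share of 0.05 of the 28721 tested, which is expected without any effect, so the rise alone shows no effect of size. Small effects of size, and effects below the spread between libraries, may be present and stay untested.

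Other splits of the libraries show which counts stand apart from chance. For oocytes against somatic cells, 1 of 40 groupings gave as many calls, the real one with 25738 against at most 1 in the others, and for cumulus against granulosa cells over all sizes 1 of 60 did, the real one with 6585 against at most 1305. These splits part libraries of 1 number, which deviate together in granulosa cells. Among splits that move all libraries of a cell type and number together, 1 of 40 and 1 of 35 gave as many, the real ones, against at most 17306 and 3779 in the others. Both shares lie under 0.05 but are the smallest that so few splits can give, and the 40 are a sample of the possible splits. Chance is thus unlikely but not excluded for both counts. The second fell to 1066 with size and number together as a block, and was 6635 with the number alone as a block. The split with 3779 exchanged the cumulus libraries of number 4 and the granulosa libraries of number 1. The single calls did not stand apart from chance. In granulosa cells 6 of 35 splits gave at least the 1 call found for medium against small and 3 of 35 for large against small, with at most 1 call in other splits. The granulosa numbers pair the libraries, and the real split parts all 4 pairs, as 7 other splits do; these gave 0 calls in both comparisons, but 8 splits are too few for a share under 0.05. The splits that reached 1 call kept some same-numbered libraries together. For cumulus against granulosa cells in small follicles 6 of 35 splits gave at least the 1 call found. The highest of these, with 1137 calls against 1 in the real split, set granulosa small 1 with the 3 cumulus libraries against granulosa small 2, 3 and 4, which points to a structure of the samples. A count of 0 is reached by all 35 splits: those comparisons gave at most 2, 1 and 1 calls in other splits for cumulus medium against small, large against medium and large against small, at most 1 for granulosa large against medium, 0, 2 and 2 for oocytes in the same order, and at most 1 for cumulus against granulosa cells in medium and in large follicles. For the difference between the large against small changes 7 of 60 groupings gave at least 1 call, with at most 2.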
